A study of Danio rerio with 14 samples.

How the data were processed

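The series comprises 14 samples of whole zebrafish embryos, grouped by assay and hours post fertilization as the sample titles give them: Ybx1 RIP-seq at 0, 2 and 4 hpf, iCLIP at 4 hpf and RIP inputs at 0 and 2 hpf with 2 samples each, and RIP-BS at 0 and 3 hpf with 1 each. There were 8 peak lists and 2 site lists, 1 per sample. The inputs have no list here and were not analysed here.

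Peak lists hold MACS2 peaks, 1 list per sample rather than of pooled replicates. Per the file headers, each peak has a pileup (signal) at its summit, a fold enrichment (a ratio), and −log10 p and q values, all set by the authors' peak caller. In the 0 and 2 hpf and RIP-BS lists the headers of the −log10 columns are spreadsheet errors, and the deposited column order was read as that of a MACS2 table. The lowest −log10 p of each deposited list was at most 3.04. The submitters' processing notes name TopHat2 2.1.1, MACS2 2.1.1 and bedtools for RIP-seq, and BWA 0.7.10 in addition for the 4 hpf RIP-seq and iCLIP samples. For RIP-BS they name MACS2 2.1.1 and bedtools. What each tool did, whether inputs served as controls and how reads with several matches were treated are not given in the sources used here. The iCLIP files deposited hold positions with a strand and a coverage, a count of reads with a lowest value of 2, and they were read with 0-based starts. Their normalization is not given. The scaffold names in the peak lists are those of Zv9. The iCLIP lists hold only chromosomes 1 to 25 and MT, so their build was inferred from their overlap with the peaks.

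No genome or annotation of Zv9 was used here, and the tables at hand pair gene names with another assembly, whose coordinates were not used. The planned comparisons of genes, of the gene lists fixed before the data were examined, of transcript regions and of sequence at sites were therefore not run. In place of genes, overlapping peaks of the 6 RIP-seq lists were joined into regions, and tests used all 135625 tiles of 10 kb on chromosomes 1 to 25, each counted for a list when it holds the midpoint of a peak or site. Tiles without any transcript are among them, which raises the odds ratio of any pair of RNA assays. The named regions follow the rule planned for genes: per pair of stages and direction, the 5 present in both replicates of one stage and neither of the other with the highest mean within-list percentile of fold. In addition the 5 tiles and strands with most shared iCLIP sites and the 5 highest folds of each RIP-BS list, and of its peaks without a match, were named. Peaks of the earlier stages without any 4 hpf peak, of the 4 hpf lists alone and of all 6 lists were ranked in the same way, which was added after the data were seen.

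A peak counted as shared when it overlapped a peak of the other list by at least 1 base. Chance overlap was measured by shifting all peaks of a chromosome by a common random offset (100 placements) and by moving each peak 5 kb to either side. Tiles were compared with Fisher's exact test (two-sided), with p-values below 1e-300 written as that. The test counts neighbouring tiles as independent, while peaks cluster, so its p-values are too small to be taken at face value. Regions of one stage only were set beside the other 2 ways to split the 4 lists. Shares of peaks per chromosome were compared between the 4 hpf and the 4 earlier lists with an exact permutation test over 15 splits. Bins of 1 Mb were compared as shares per 10000 peaks with 0.2 added to both sides of a ratio. Ranks by fold were taken within a list. Where pileups, folds or backgrounds of different lists are set beside each other, they are not corrected for depth. The background of a list is the most frequent value of (pileup + 1) / fold − 1, which takes fold as a ratio with 1 added to both terms. This form is an assumption, and library depth itself is unknown. Confidence intervals are exact Clopper-Pearson 95% intervals and cover counting error only.

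The functions were tested on simulated data. For each pair of stages, 200 regions per side were planted among 60000 that every list held with the same chance. That chance was set well above the share of peaks that real replicates had in common. For 0 against 2, 2 against 4 and 0 against 4 hpf alike, 95.5% of the first and 97.5% of the second side were found. Another 113 to 149 regions per side were called without being planted. The check therefore does not give the rate of false calls in the real lists, where replicates share fewer peaks. Independent lists as long as those of 0, 2 and 4 hpf gave tile odds ratios of 1.01, 0.994 and 1.01. Alternatives were a reciprocal overlap of 50%, the same number of top peaks per RIP-seq list (42200), peaks at or above each list's median fold, each replicate left out, and for iCLIP a distance of 10 bases and sites at or above the median coverage. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Peaks on unplaced scaffolds were left out of all comparisons of the report.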

Results

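Ybx1 is a cold-shock-domain protein that binds RNA, and the series asked where it binds in the early zebrafish embryo and how its binding relates to 5-methylcytosine. Whole embryos of the AB strain were collected at 0, 2, 3 or 4 hours post fertilization (hpf). RNA immunoprecipitation with an antibody against Ybx1 followed by sequencing (RIP-seq) was done at 0, 2 and 4 hpf with 2 replicates each. iCLIP, which maps the base next to an RNA-protein crosslink, was done at 4 hpf with 2 replicates. RIP-BS, in which the pulled-down RNA is treated with bisulfite before sequencing, was done at 0 and 3 hpf with 1 library each. Of the 14 samples, 10 had a list of peaks or sites that was analysed here. The 4 input libraries, from 0 and 2 hpf, were not analysed here.

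The RIP-seq lists held 60462 and 47736 peaks at 0 hpf, 50405 and 65304 at 2 hpf, and 43118 and 45672 at 4 hpf, replicate 1 first. The iCLIP lists held 33555 and 34045 sites with a summed coverage of 435101 and 479370 reads. The RIP-BS lists held 30210 peaks at 0 hpf and 22754 at 3 hpf. Read totals are not given in the lists, so the depth of the peak libraries is unknown. The background implied by a peak's pileup and fold took 1 value in a large share of the peaks of each list (39.0 to 74.6%), and it can serve as a rough guide to depth. It was 1.79 and 4.26 at 0 hpf, 1.11 and 4.35 at 2 hpf, 0.57 and 0.61 at 4 hpf, and 5.12 and 5.29 in the RIP-BS lists of 0 and 3 hpf. No peak of the 4 hpf RIP-seq and RIP-BS lists had a fold over 50, while 371, 2263, 149 and 3156 peaks did in the 0 hpf and 2 hpf lists. The 4 hpf lists therefore differ from the earlier ones in the range of fold as well as in stage. Whether a list was called against an input is not given, so a fold or a peak need not mean the same at 4 hpf as before. The labels do not say that replicates were separate clutches, so the spread between them may be technical. Positions are those of the Zv9 build, on chromosomes 1 to 25 unless said otherwise, and no gene annotation of that build was used here, so regions are given without gene names.

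The replicate lists of a stage shared most of their peaks when 1 shared base counted as overlap. With a reciprocal overlap of 50% the mean shares were 40.8% at 0 hpf, 32.6% at 2 hpf and 50.8% at 4 hpf. At 4 hpf, 61.4% of replicate 1 peaks overlapped a replicate 2 peak and 58.8% the other way (mean 60.1%). At 0 hpf the shares were 59.9 and 71.4% (mean 65.7%), and at 2 hpf 79.1 and 54.8% (mean 66.9%). Each stage has 1 pair of lists, so no spread can be given. Randomly placed lists gave 1.85% at 4 hpf, 3.06% at 0 hpf and 4.00% at 2 hpf, the highest of 100 placements being 2.07%, 3.61% and 4.50%. Moved by 5 kb, the replicate 1 peaks still overlapped replicate 2 in 6.63%, 15.5% and 19.7% of cases at 4, 0 and 2 hpf. In 10 kb tiles the odds ratios of the replicates were 51.8 at 4 hpf, 64.6 at 0 hpf and 59.6 at 2 hpf (Fisher's exact test, two-sided, p = 1e-300 for each, the smallest value written). All tiles of the genome entered, transcribed or not, so high odds ratios were found for every pair tested, from 23.8 to 94.6. Neighbouring tiles are not independent, so the p-values of all tile tests overstate the evidence.

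Some 0 and 2 hpf lists resembled each other by replicate number more than by stage, most of all the replicate 2 lists. Replicate 2 of 0 hpf and replicate 2 of 2 hpf had a Jaccard index (shared bases over bases in either list) of 0.679, and 97.0% of the peaks of the former overlapped the latter. The replicate 1 lists of these stages had an index of 0.402. Within a stage the index was 0.363 at 0 hpf and 0.301 at 2 hpf, both lower than either pair of the same number. Lists that differed in stage and number had 0.399 (replicate 1 of 0 hpf with replicate 2 of 2 hpf) and 0.289, so the replicate 1 pair barely exceeded the former. The 4 hpf lists had 0.392 with each other and 0.142 to 0.204 with the earlier lists.

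**Figure D1:**
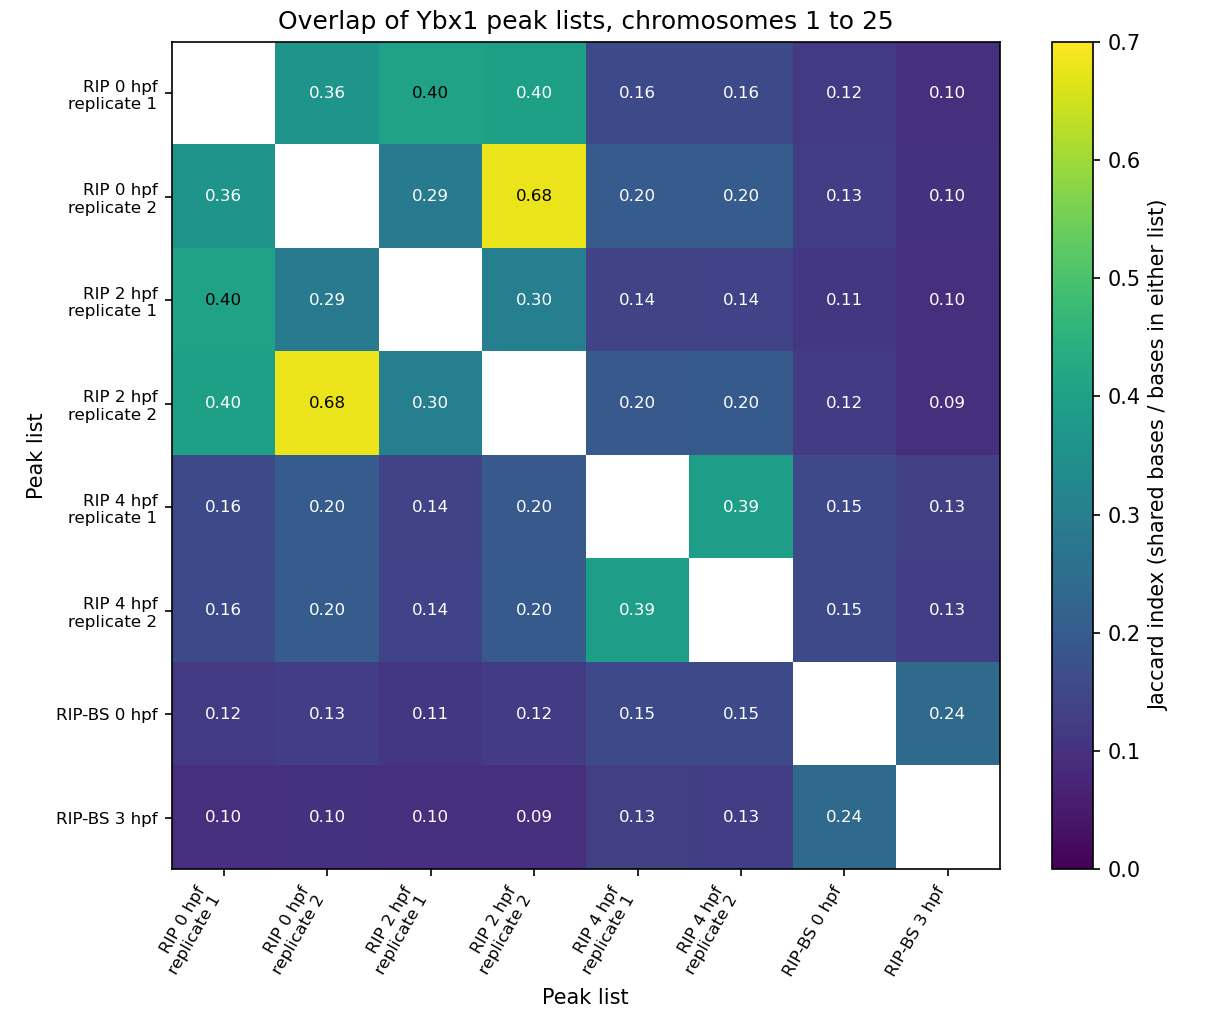
Jaccard index of every pair of the 8 Ybx1 peak lists (both axes, 1 list per row and column, shade and printed value give the index). The pair of replicate 2 lists from 0 and 2 hpf stands highest at 0.679, and the 4 hpf lists share at most 0.204 with an earlier list.

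Joining overlapping peaks of the 6 RIP-seq lists gave 98923 regions, of which 32822 were present in both replicates at 0 hpf, 34959 at 2 hpf and 24339 at 4 hpf. All 6 lists held 12734 of them. Those with the highest fold ranks in all lists lay on chromosome 8 at 2668692 to 2669243, chromosome 6 at 28810251 to 28811356, chromosome 7 at 55231055 to 55231859, chromosome 14 at 53369526 to 53370053 and chromosome 16 at 58353335 to 58354092. The region on chromosome 8 had folds of 72.6 and 218 at 0 hpf, 54.5 and 115 at 2 hpf, and 30.3 and 31.3 at 4 hpf. iCLIP sites lay in each of these 5 regions in both replicates, with a coverage of 139 and 414 in the one on chromosome 16. The counts of a single replicate were 55546 and 45005 regions at 0 hpf, 44990 and 63311 at 2 hpf, and 37731 and 39584 at 4 hpf.

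Between 0 and 2 hpf, few regions separated the stages. Peaks in both 0 hpf lists and neither 2 hpf list marked 244 regions, and the reverse marked 2171. Split by replicate number, the same 4 lists gave 11276 regions, and the crossed split gave 4682, so the 2415 of the stage split lay below both. The difference between 0 and 2 hpf was therefore not larger than the spread between replicates. The 5 regions ranked highest among those of both 0 hpf lists and neither 2 hpf list were on chromosome 4 (44015246 to 44015539, folds of 58.6 and 20.1), chromosome 10 (34621542 to 34621983), chromosome 9 (22105713 to 22106395), chromosome 1 (20708413 to 20708696) and chromosome 5 (62901869 to 62902322). Those of both 2 hpf lists and neither 0 hpf list were on chromosome 12 (18670009 to 18670518, folds of 11.0 and 34.1), chromosome 7 (39297240 to 39298029), chromosome 5 (18217284 to 18217536), chromosome 13 (36833959 to 36834456) and chromosome 10 (36180772 to 36181247). The first of these and the one on chromosome 13 also had peaks in both 4 hpf lists. With the same number of top peaks per list the 2 directions were nearly equal, at 880 and 869 regions. The replicates decided the direction: without replicate 1 there were 1378 regions of 0 and not 2 hpf and 19684 of 2 and not 0 hpf, and without replicate 2 there were 22531 and 11975.

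From 2 to 4 hpf the lists parted by stage. There were 11494 regions in both 2 hpf lists and neither 4 hpf list, and 3859 in both 4 hpf lists and neither 2 hpf list. The total of 15353 exceeded those of the other 2 splits of these lists, 3921 and 3699. Between 0 and 4 hpf there were 10023 and 4275 regions, a total of 14298 against 3457 and 3528 for the other splits. With the same number of top peaks per list the counts were closer, 6438 and 5132 for 2 against 4 hpf and 7012 and 4943 for 0 against 4 hpf. Single replicates gave more regions in the same direction, for 2 against 4 hpf 35752 and 12025 without replicate 1 and 24683 and 17424 without replicate 2, and for 0 against 4 hpf 22310 and 16889, and 31921 and 14106. Only 3 splits of 4 lists exist, too few for a test. Peaks present in all 4 earlier lists and neither 4 hpf list marked 5832 regions, and the 4 hpf pair alone marked 3527.

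**Figure D2:**
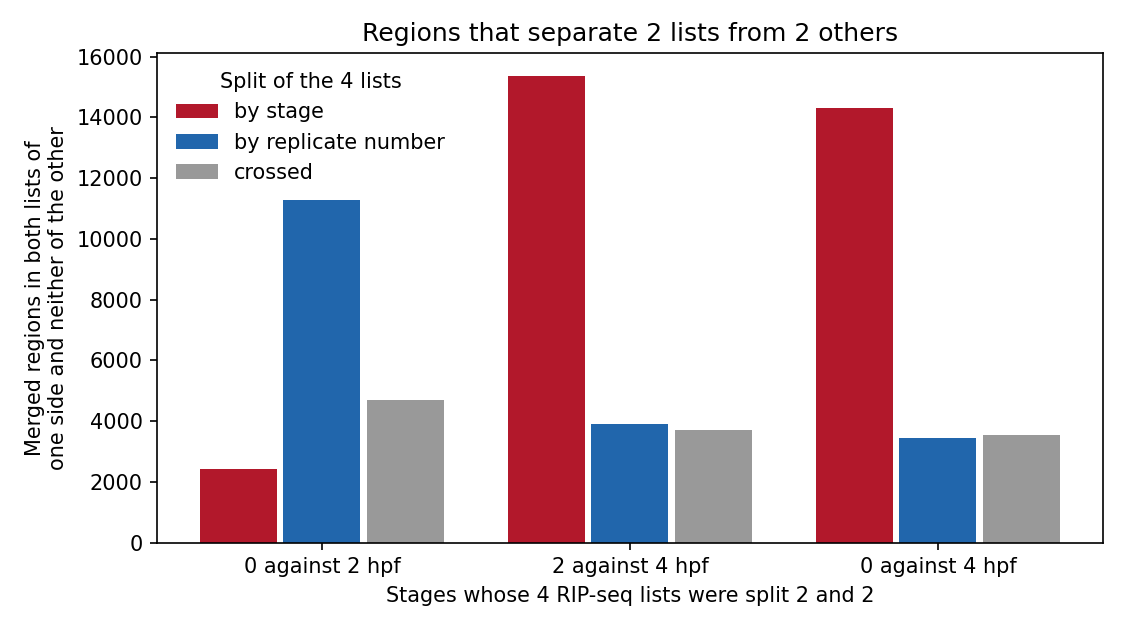
Number of merged regions (vertical axis) found in both lists of one side and in neither of the other, for the 3 ways to split the 4 RIP-seq lists of a pair of stages (horizontal axis, colours give the split). The stage split is the lowest for 0 against 2 hpf at 2415 and the highest for the pairs with 4 hpf at 15353 and 14298.

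The regions of the earlier stages that ranked highest among those without a 4 hpf peak had strong folds, which follows from the ranking by fold. A region on chromosome 12 (11710147 to 11710670) had folds of 64.9 and 44.4 at 0 hpf and of 42.6 and 112 at 2 hpf. One on chromosome 13 (2106005 to 2106367) had 39.2 and 119 at 2 hpf. The others that ranked highest at 2 hpf were on chromosome 10 (16061118 to 16061578), chromosome 3 (24894055 to 24894946) and chromosome 17 (23060685 to 23061125). At 0 hpf the ranking named regions on chromosome 1 (46046272 to 46047123), chromosome 25 (5035630 to 5036356), chromosome 15 (1549406 to 1550266), chromosome 10 (30674773 to 30675175) and chromosome 20 (29605720 to 29606226). At least 1 of the 4 hpf iCLIP lists held sites in 8 of these 10 regions, among them the one on chromosome 15 with a coverage of 9 and 37 reads. These 10 were picked for high fold. Of all regions in the 4 earlier lists and neither 4 hpf list, only 17.6 and 16.7% held a site of iCLIP replicates 1 and 2.

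At 4 hpf, the same 5 regions ranked highest against both earlier stages, and none had a peak in any of the 4 earlier lists. They lay on chromosome 18 (18895226 to 18895461), on chromosome 4 (56443024 to 56443261, 52014479 to 52014726 and 48253224 to 48253448) and on chromosome 1 (6024263 to 6024524). They were 225 to 262 bases wide, with pileups from 1904 to 5662 and folds of 48.7 to 49.6, near the bound of 50. Sites of iCLIP with a coverage of 28 and 15 reads lay in the region on chromosome 18, all on the minus strand. The regions on chromosome 4 from 56443024 and from 48253224 held no site in either replicate, and the other 2 held a site in 1 replicate only. When peaks up to 5 kb apart were joined, the direction turned, with 1189 regions of 2 and not 4 hpf and 2395 of 4 and not 2 hpf, and 923 and 2464 for 0 and 4 hpf. Stage, the tools named by the submitters and the range of fold change together at 4 hpf and cannot be told apart.

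Chromosome 4 differed most in its share of peaks at 4 hpf. A run of 28 bins of 1 Mb, from 30 to 58 Mb, held 1.42% ± 0.0206 of the 4 hpf peaks (SD, n = 2) and 0.125% ± 0.0896 of the peaks of the 4 earlier lists (SD, n = 4), a ratio of 11.4. The interval was chosen from these lists, as the longest run of bins on chromosome 4 over 3-fold higher at 4 hpf, so a high ratio follows in part from the choice. Without replicate 1 of each stage the ratio was 28.2 and without replicate 2 it was 7.06. The interval held 593 and 641 peaks at 4 hpf, 127 and 10 at 0 hpf, and 92 and 52 at 2 hpf. Chromosome 4 up to 30 Mb held 2.21 and 2.28% of the 4 hpf peaks and 2.27 to 2.36% of the earlier ones. Over the whole chromosome the share was 3.97% ± 0.0865 (n = 2) against 2.66% ± 0.139 (n = 4), and both 4 hpf lists exceeded all 4 earlier ones (exact permutation test, two-sided, p = 0.0667, the smallest that 15 splits allow, 0.208 after Benjamini-Hochberg adjustment over 25 chromosomes). The test takes the 6 lists as exchangeable, while their overlaps show that some are closer than others. The same p was reached by 7 other chromosomes, 2 higher and 5 lower at 4 hpf. Every other chromosome had a ratio between 0.937 and 1.07. In the genome, 54 bins were higher in both 4 hpf lists than in all earlier ones and over 3-fold higher in the ratio of means. Of these, 30 were on chromosome 4, and no bin was over 3-fold lower. Chromosome 4 has 63 of the 1369 bins and held 12.8% of the regions found in the 4 hpf pair alone.

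Of the 4 hpf peaks inside the interval, 60.5% of replicate 1 overlapped replicate 2 and 56.3% the other way. Their median fold was 6.35 and 6.20, against 6.05 for the whole replicate 2 list. The interval held 330 of the 3527 regions found in the 4 hpf pair alone (9.36%). In the iCLIP lists of the same stage the interval held 0.367 and 0.277% of sites (95% exact Clopper-Pearson intervals 0.305 to 0.438 and 0.224 to 0.339). The RIP-BS lists had 0.536% at 0 hpf (0.456 to 0.626) and 0.523% at 3 hpf (0.433 to 0.627). These intervals cover counting error only.

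**Figure D3:**
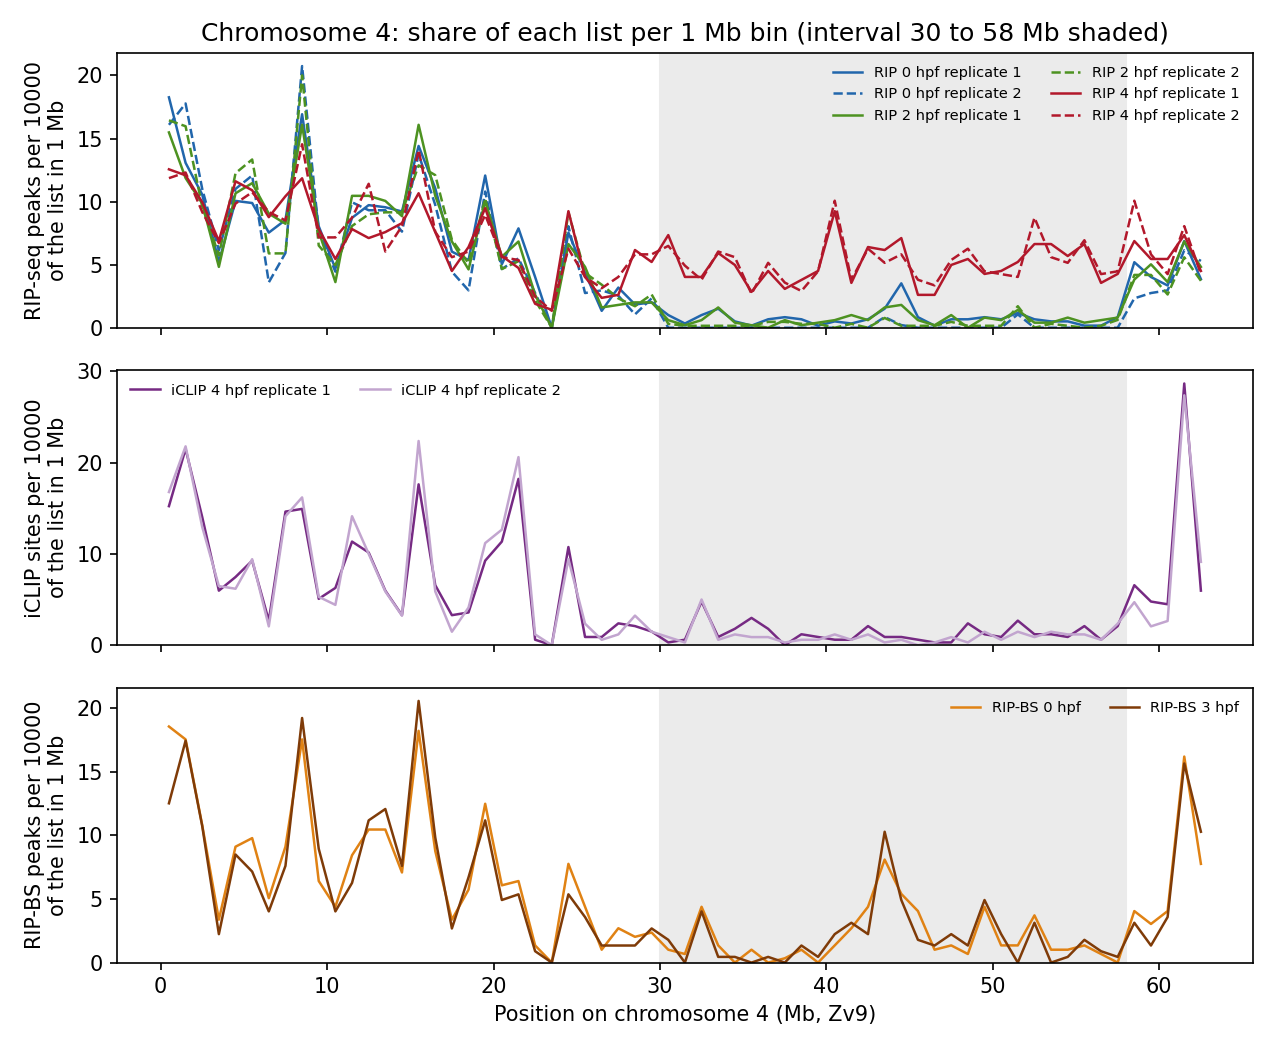
Peaks or sites per 10000 of each list (vertical axes) in 1 Mb bins along chromosome 4 (horizontal axis, Mb, Zv9), with RIP-seq, iCLIP and RIP-BS in separate panels, 1 line per library, and the interval from 30 to 58 Mb shaded. Both 4 hpf RIP-seq lines stay up through the interval, with 593 and 641 peaks, where the 4 earlier lists fall to between 10 and 127.

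Crosslink sites at 4 hpf were partly shared between the iCLIP replicates. On chromosomes 1 to 25 the lists held 33484 and 33972 positions, and 7887 were the same position and strand, 23.6 and 23.2% of the lists. Replicate 1 sites moved along the genome gave 0.0411%, and the opposite strand gave 0.0627%. Within 50 bases, 59.4 and 59.8% were shared, against 4.30% for moved sites and 2.36% for the opposite strand at that distance. Sites with a coverage of 20 or more were found again in 63.5 and 65.4% of cases and those with 2 to 4 in 6.56 and 7.38%. Across the shared sites, which are not independent replicates, coverage had a Spearman rho of 0.765.

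The 10 kb tiles with the most shared sites of a strand were on chromosome 4 (61290001 to 61300000, 33 sites on the plus and 19 on the minus strand), chromosome 23 (45160001 to 45170000, 31 on the minus strand), chromosome 22 (170001 to 180000, 20 on the plus strand) and chromosome 10 (37870001 to 37880000, 15 on the minus strand). Each of these 4 places also held peaks in both 4 hpf RIP-seq lists. In merged regions with at least 5 sites, all sites lay on 1 strand in 80.6% of 809 regions for replicate 1 and 76.6% of 978 for replicate 2.

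iCLIP sites fell inside RIP-seq peaks of the same stage far more often than the same sites moved by 5 kb. In the 4 hpf lists, 48.6% ± 2.32 of sites lay in replicate 1 peaks and 49.0% ± 2.08 in replicate 2 peaks (SD, n = 2 iCLIP lists), against 4.15 and 4.09% after the move. Larger shares lay in the earlier lists, up to 82.6% ± 1.03 in replicate 2 of 2 hpf, where the moved sites gave 14.5%. As means over the 2 iCLIP lists, the ratio to the moved sites was at least 11.7 for the 4 hpf lists and 5.71 to 6.43 for the earlier ones. This gap depends on the measure of chance. Sites placed at random fell in 4 hpf peaks in 0.901 to 0.974% of cases and in replicate 1 of 2 hpf in 1.16%, where 55.7% of sites lay. With the same number of top peaks per RIP-seq list, the earlier lists still held more sites, 53.5 to 72.4% against 48.6 and 49.0%. In 10 kb tiles, 8603 of the 10040 tiles with sites in both iCLIP lists had peaks in both 4 hpf RIP-seq lists, where 1464 were expected (odds ratio 61.3, Fisher's exact test, two-sided, p = 1e-300). Among the 37961 tiles with a peak in a list of the earlier stages or of RIP-BS, 8479 were shared where 4447 were expected, and the odds ratio was 16.1. Without 1 replicate of each assay the odds ratio was 33.0 to 35.0. Within the 4 hpf peaks, 22.4 to 23.9% of sites lay within 50 bases of the summit, and an even spread over the same peaks would give 27.5 to 28.4%.

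**Figure D4:**
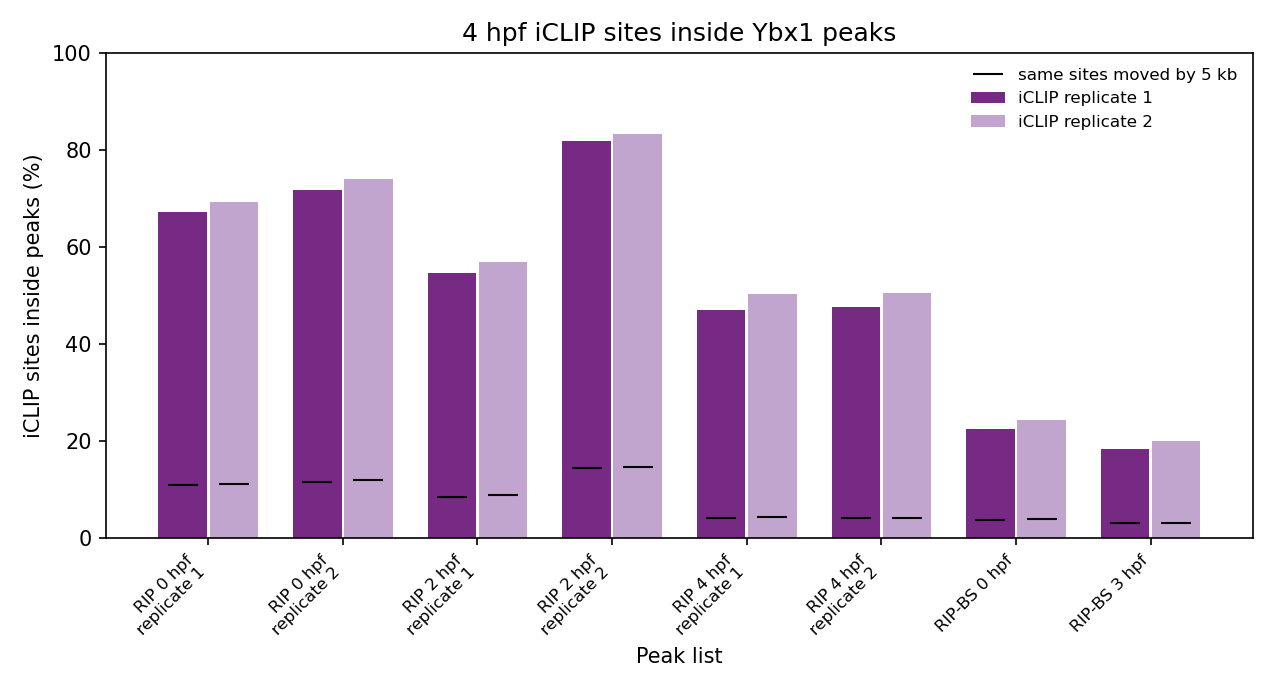
Share of iCLIP sites (vertical axis, percent) that lie inside the peaks of each list (horizontal axis), as a bar for each iCLIP replicate, with a black line for the same sites moved by 5 kb. Shares run up to 83.3% in replicate 2 of 2 hpf and are 46.9 to 50.5% in the 4 hpf lists, where the moved sites fall lowest among the RIP-seq lists.

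Regions found in all 6 RIP-seq lists held a site of iCLIP replicate 2 in 58.5% of cases, and in both replicates 5.93 times as often as the same regions moved by 5 kb. Regions of the 4 earlier lists without a 4 hpf peak held one in 17.6 and 16.7% of cases, against 8.80 and 8.48% after the move. Regions of the 4 hpf pair alone held one in 8.53 and 8.93% of cases, against 0.610 and 0.595%. Their median widths differed, at 856, 469 and 211 bases.

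The RIP-BS lists hold peaks of bisulfite-treated RNA and give no methylation level. With 1 library per stage, there was no replicate check. Of the 0 hpf peaks 40.4% overlapped the 3 hpf list (95% exact Clopper-Pearson interval 39.8 to 40.9), and 53.4% the other way (52.7 to 54.0), against 5.23 and 6.95% after a move of 5 kb. RIP-BS peaks of 0 hpf overlapped the RIP-seq lists of that stage in 60.6 and 60.3% of cases and those of 2 hpf in 48.7 and 75.7%. Those of 3 hpf overlapped the 2 hpf lists in 51.2 and 76.4% and the 4 hpf lists in 44.9 and 45.8%. Relative to the same 3 hpf peaks moved by 5 kb, this order was reversed. The ratios were 4.05 and 3.95 for the 2 hpf lists and 5.67 and 5.73 for the 4 hpf lists. For RIP-BS peaks of 0 hpf the ratios were 3.96 to 4.07 with the 0 and 2 hpf lists and 5.65 and 5.67 with the 4 hpf lists. For 3 hpf, the tile odds ratios that follow kept the order of the raw shares. RIP-BS tiles of 10 kb were compared with the tiles that held peaks of both RIP-seq replicates. The odds ratios were 33.6 for 0 hpf with 0 hpf and 37.9 for 0 hpf with 2 hpf. They were 34.5 for 3 hpf with 2 hpf and 25.2 for 3 hpf with 4 hpf (Fisher's exact test, two-sided, p = 1e-300 for all of these pairs). Among tiles with a peak or site of a list outside the test, the ratios were 7.61 for 0 hpf with 0 hpf, 8.30 for 3 hpf with 2 hpf and 5.82 for 3 hpf with 4 hpf. Some RIP-seq list overlapped 86.3% of the 0 hpf and 87.0% of the 3 hpf RIP-BS peaks.

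The highest folds in the 0 hpf RIP-BS list were on chromosome 4 (43949564 to 43949763, fold 49.8, and 61356341 to 61356543), chromosome 8 (37693747 to 37693971), chromosome 1 (3370530 to 3370799) and chromosome 14 (43000425 to 43000781). At 3 hpf the list was led by the same place on chromosome 8 (fold 49.7), followed by chromosome 4 at 61342778 to 61342989, chromosome 3 at 30399871 to 30400240, and the places on chromosomes 1 and 4 named for 0 hpf. All of these overlapped a peak of the other RIP-BS list. Those on chromosome 4 overlapped no peak of any RIP-seq list, while those on the other chromosomes overlapped peaks of 2 to 6 RIP-seq lists. Peaks of 0 hpf without one had folds of at most 44.5, led by chromosome 14 at 22825615 to 22825921, chromosome 4 at 61736330 to 61736544, chromosome 21 at 15578770 to 15579047, chromosome 9 at 28901371 to 28901757 and chromosome 12 at 15071814 to 15072120. Those of 3 hpf were led by chromosome 4 at 61459180 to 61459400 (fold 47.8), chromosome 2 at 35454469 to 35454772, chromosome 17 at 762391 to 762612, chromosome 4 at 44008054 to 44008255 and chromosome 10 at 15298039 to 15298294. Of these peaks without a match, at 0 and 3 hpf, those on chromosomes 4 and 17 overlapped no RIP-seq list and the others 4 to 6.

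The mitochondrial genome, left out of the comparisons above, carried very high signal. Its highest peak had a pileup of 38618 and 2041984 at 0 hpf, 47669 and 1462534 at 2 hpf, and 72081 and 72424 at 4 hpf, each covering part of positions 952 to 3729. iCLIP put 71 and 73 sites there with 29676 and 24917 reads, 6.82 and 5.20% of all coverage. Of these reads 97.8 and 90.5% lay between positions 1972 and 3729, and 95.2 and 93.2% of the mitochondrial reads were on the plus strand. A second place, chosen after its values were seen, was chromosome 4 from 61280001 to 61310000. Its highest pileup was 1060960 and 53 at 0 hpf, 644378 and 107 at 2 hpf, 316982 and 335845 at 4 hpf, and 3361189 and 3801875 in the RIP-BS lists. It took 4.40 and 4.34% of iCLIP coverage.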

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

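The tests of the 4 hpf processing, of embryo-made RNA and of sparse bins on chromosome 4 were chosen after the result was seen, the reading of the abundant-RNA test was changed after its value was seen, and the depth test was chosen after the background of each list was known. Peaks on unplaced scaffolds are given because the report's comparisons do not use them, and their presence alone is nothing unusual. There were 787 and 492 at 0 hpf, 672 and 827 at 2 hpf, 910 and 975 at 4 hpf, and 557 and 376 in the RIP-BS lists of 0 and 3 hpf. Of 447 scaffolds, 106 had more peaks in both 4 hpf lists than in any of the 4 earlier RIP-seq lists, 60 of them with a single peak in a 4 hpf list, and 14 had fewer in both than in all 4. Zv9_scaffold3530 had 44 and 49 peaks at 4 hpf, 0 to 2 in the 4 earlier RIP-seq lists, and 9 and 6 in the RIP-BS lists of 0 and 3 hpf.

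The share of peaks on chromosome 4 from 30 to 58 Mb was 11.4 times higher at 4 hpf. The long arm of this chromosome is known as heterochromatic and rich in repeats. Among peaks at or above each list's median fold the 4 hpf share did not fall (at least 1.51%, from 1.41 and 1.43%). The ratio of 23.3 there owes most to a lower earlier share (at most 0.123%). These values argue against peaks of the lowest folds as the cause, but not against background peaks in general. The median fold of the 4 hpf lists was only 6 and 6.05, and their median pileup was 12, against 10 inside the interval. RNA made by the embryo by 4 hpf and bound by Ybx1 may contribute and stays open: 4 hpf peaks of the interval carried an iCLIP site 0.902 times as often as 4 hpf peaks elsewhere without an earlier peak (3.76 against 4.17%, and 0.242% after a move of 5 kb), but 23.2 to 24.0% of all 4 hpf peaks carried one. Different processing of the 4 hpf lists by the authors stays open too, such as calling without an input. A peak may then reflect abundant RNA rather than enrichment. The RIP-BS lists, with the same bound on fold, reached 0.378 of the 4 hpf share at 0 hpf, below the level set for a full cause. That was 4.58 times the mean of the RIP-seq lists of 0 hpf, or 2.52 and 25.3 times replicates 1 and 2 alone. BWA is named for 4 hpf RIP-seq and not for RIP-BS, so these lists cannot decide on a difference in alignment.

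The 0 and 2 hpf lists had a higher mean Jaccard index by replicate number than by stage, carried by the replicate 2 pair (0.679), since the replicate 1 pair (0.402) was hardly closer than replicate 1 of 0 hpf and replicate 2 of 2 hpf (0.399). Wider peaks in the replicate 2 lists do not account for it, since the share of summits within 100 bases was 29.0 percentage points higher for the same number (59.0 against 30.0%). Greater depth of replicate 2 could contribute: its background was 4.26 and 4.35 against 1.79 and 1.11, but 76.6% of the better-scored replicate 1 peaks of 0 hpf and 90.0% of those of 2 hpf overlapped replicate 2, which lies between what was set beforehand for no and for full effect. Leaving out 62 tiles with the highest pileups changed the difference of the mean Jaccard indices by -0.000354, which had been set beforehand as evidence against abundant RNAs but decides nothing, because the tiles hold only 0.200% of the peaks. A different share of reads from abundant RNAs therefore stays open, and replicate 1 and 2 differed there, with pileups of 1060960 and 53 at the chromosome 4 place from 61280001 and 38618 and 2041984 on MT at 0 hpf.

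Of the regions in all 4 earlier lists, 5832 had no 4 hpf peak and 12734 had peaks in both 4 hpf lists. Lower sensitivity of the 4 hpf lists may explain part of this. Those without a 4 hpf peak ranked lower in earlier fold by 12.7 percentile points (medians 56.3 and 69.0), and the 4 hpf background was the lowest. The rank is that of a region's best peak, however, and the regions with 4 hpf peaks were wider (median 856 against 469 bases), which favours higher ranks. Lower sensitivity therefore stays open, and the ranks cannot decide it. Loss of the RNA or of Ybx1 binding could not be told apart from it, because these regions held a 4 hpf iCLIP site 1.97 and 2.00 times as often as the moved regions, between what was set beforehand for loss and for binding kept.

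A pair of further explanations was tested and left out of the weighing above after the values were seen. One was more peaks in sparse parts of the genome. The 10% of bins with the fewest peaks in the earlier lists were picked without regard to 4 hpf. All 28 of them on chromosome 4 were over 3-fold higher at 4 hpf, with a median ratio of 9.23. Elsewhere 24 of 109 were, with a median of 1.95. The chromosome 4 bins are mostly those of the interval, which was chosen for bins over 3-fold higher at 4 hpf. Their count and median follow in part from that choice, so the contrast cannot decide how much of the rise sparse parts explain. Unequal list lengths would end the pairing by number once lists are equal, but the difference of the mean Jaccard indices was 0.240 with the same number of top peaks and 0.208 with all.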

How the results depend on the processing

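Settings with peaks joined within 5 kb, with 2 kb tiles or only tiles of lists outside the test, and all alternatives for chromosome 4 and for pairing by number were chosen after seeing the data, as were top peaks in RIP-BS and the median-fold setting for RIP-BS against RIP-seq. Odds ratios of iCLIP and RIP-BS with RIP-seq kept their direction and p-values under the threshold in all alternatives run, between 5.82 and 79.9, and were lowest among tiles with a peak or site of a list outside the test. The stage split stayed below the other splits for 0 against 2 hpf and above them for the pairs with 4 hpf with top peaks, with peaks at or above the median fold and with peaks joined within 5 kb. With the replicate number as a replicate block, the chromosome 4 ratio within each number had a geometric mean of 14.1. Counts of regions come from no fitted test and had no block. The samples share only a number, and the difference of replicate 1 and 2 over regions had a correlation of 0.249 between 0 and 2 hpf, 0.00407 between 0 and 4 hpf and -0.00383 between 2 and 4 hpf. Not run for lack of a Zv9 annotation or genome were gene spans, the protein-coding background, length-matched lists, transcript regions and sequence windows, and the read minimum of RIP-BS did not apply to peaks. Where a value moved, the cause was not tested unless fewer peaks or libraries entered.

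With a reciprocal overlap of 50% the replicates shared 40.8% at 0 hpf, 32.6% at 2 hpf and 50.8% at 4 hpf, and the RIP-BS lists 36.3%. At or above the median fold they shared 50.7% at 0 hpf, 52.3% at 2 hpf and 64.6% at 4 hpf, and RIP-BS 33.4%. With the same number of top peaks the shares were 64.3%, 62.3% and 61.4%, and 43.7% for RIP-BS. iCLIP replicates shared 36.6% within 10 bases and 31.9% at or above the median coverage. The excess of the same-number over the same-stage Jaccard index stayed between 0.208 and 0.245. The depth of the peak libraries is unknown, so a peak missing from a list may be one that its depth could not show. The chromosome 4 ratio was 23.3 at or above the median fold and 7.06 to 28.2 without 1 replicate.

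Regions per stage fell to 13361, 14449 and 13737 at 0, 2 and 4 hpf at or above the median fold and to 10888, 11865 and 13033 with peaks joined. With 1 replicate they were 45005 to 55546, 44990 to 63311 and 37731 to 39584. Regions of 0 and not 2 hpf numbered 880 with top peaks, 500 at or above the median fold, 63 joined and 1378 to 22531 with 1 replicate, from 244. Those of 2 and not 0 hpf numbered 869, 1161, 401 and 11975 to 19684, from 2171. Those of 2 and not 4 hpf numbered 6438, 6104, 1189 and 24683 to 35752, from 11494. Those of 0 and not 4 hpf numbered 5514 at or above the median fold, 923 joined and 22310 to 31921 with 1 replicate, from 10023. With top peaks those of 0 and not 4 hpf numbered 7012. Those of 4 and not 2 hpf numbered 2395 joined and 12025 to 17424 with 1 replicate, from 3859, and those of 4 and not 0 hpf 2464 and 14106 to 16889, from 4275. Joining thus left more regions of 4 hpf that the earlier stage lacked than the reverse.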

Other observations

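All comparisons in this part were chosen after the data were seen. Outside chromosome 4, 24 bins of 1 Mb were higher in both 4 hpf lists than in all earlier ones and over 3-fold higher in the ratio of means. The one with the highest ratio, chromosome 8 from 40000001 to 41000000, had 25 and 23 peaks at 4 hpf, 4 and 0 at 0 hpf and 3 and 0 at 2 hpf, with 6 and 3 iCLIP sites. Chromosome 6 from 5000001 to 6000000 had 8 and 7 peaks at 4 hpf, none in the earlier lists and no iCLIP site. Over all 1369 bins, 18.7% were higher in both 4 hpf lists than in all 4 earlier ones and 13.2% lower, while exchangeable lists would give 6.67% for each. Some of these lists resemble each other, so the share that chance gives is higher and not known.

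In the 4 hpf RIP-seq and both RIP-BS lists, every peak had a fold within the bound that its own pileup spread over 10 kb would set, which tends to 50 for a width of 200 bases. In the 0 and 2 hpf lists 93.0 to 97.7% of peaks did. Such a bound holds where the background is taken from the list's own reads. The 1320 to 4592 peaks over it in each 0 and 2 hpf list, with folds up to 13407, could not arise on such a background. Under the assumed form of fold, the earlier lists were therefore not called on the same kind of background as the 4 hpf lists. Whether an input was used for any list is not given.

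The highest iCLIP coverage outside MT differed between the replicates. Replicate 1 had 4644 reads on the plus strand of chromosome 20 at 51537212 and replicate 2 had 4527 on that of chromosome 13 at 176557.

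Of the regions in all 6 RIP-seq lists, 57.8% held a RIP-BS peak of 0 hpf and 48.4% one of 3 hpf, and of the regions of the 4 hpf pair alone 6.38 and 5.19% did. After a move of 5 kb the shares were 16.0 and 13.0% for all 6 lists, and for the 4 hpf pair that of 3 hpf was 1.05%. In the regions of the 4 earlier lists only, the shares were 39.8% (95% exact Clopper-Pearson interval 38.5 to 41.1) and 30.5% (29.3 to 31.7), and 13.3 and 10.7% after the move. The regions differ in width, and relative to the moved regions the 4 hpf pair had the highest share of these classes for both RIP-BS lists, the reverse of the raw shares.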
